A study of Mus musculus with 24 samples.

How the data were processed

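RNA was sequenced from brain tissue of C57BL/6N mice that carried intact Shank2 (wild type, WT) or a Shank2 knock-out (KO) at postnatal day 14 (P14) or postnatal day 25 (P25). The 24 libraries form 4 groups of 6, and the labels mark 3 libraries of each group as a second batch. The other 3 carry no batch mark and were taken as the first batch. Per the labels' protocols, libraries were made with an Illumina TruSeq version 2 RNA kit. Per the submitters' processing notes, the tools were Trimmomatic 0.35 for trimming, TopHat2 2.1.0 for alignment, HTSeq for counting reads per gene and DESeq2, on genome build GRCm38; versions of HTSeq and DESeq2, the gene annotation release, the strand setting and any filter are not given in the sources used here. The deposited values are a signal per gene: read counts divided by 1 size factor per library, in a single table of 46078 Ensembl gene identifiers, and this unit was read from the values themselves. Every deposited value is a whole multiple of 1 step in its library, so the read counts were recovered: 100% of the nonzero values came out whole within 0.01. The recovered totals ran from 27552844 to 40787586 reads per library and the size factors from 0.825 to 1.223. No sample column was left unused (0 columns). Of the identifiers, 45143 (98.0%) were matched to symbols and positions in GENCODE M21 on GRCm38, and 935 had no symbol.

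The analysis plan had been written for read counts with edgeR as the test, and it named a fallback for normalised values. Because the table holds normalised values, the fallback became the test used throughout: limma with an intensity trend on log2(value + 1), for the 18267 genes with a mean value of at least 10. A fold change on this scale understates the change of genes with low values. The model held 4 group means and 1 batch term per age, with 18 residual degrees of freedom. Age contrasts were taken at the mean of both batches. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Contrasts were KO against WT at each age, the difference of those effects between the ages, and P25 against P14 in each genotype. A genotype by batch term was tested in the same model. The design text gives 6 mice per group.

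Gene lists were fixed before the data were examined, as were the tests, the other settings to be tried and the rule for naming genes. There were 41 lists of synaptic, regional, cell type, metabolic and stress genes, of which 40 had at least 5 tested members and entered the tests; the list of sex-linked genes was read only as levels. Lists were tested with camera at a preset correlation between genes of 0.01, on log2(value + 1) where the plan named log-CPM. Camera with an estimated correlation and fry gave second readings. Camera compares a list with all other genes; fry's directional test asks whether the genes of a list move one way on balance and makes no such comparison. Named genes were the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 1 CPM and changed with the same sign in both batches. Where fewer than 5 genes passed, the 5 with the smallest p were named. Shank2, Shank1, Shank3, Grin1, Grin2a and Grin2b were always named in the KO comparisons, as were members of each list with the smallest p. The rule allowed up to 4 members per list; 2 are named in the KO comparisons and 3 in the age comparison, a reduction made after the longer table had been seen. Results of some single genes are not reported here, so a few lists name fewer members. Shank2 and the gene with the smallest p were also tested by a 2-sided exact permutation test that exchanges KO and WT within batches (400 arrangements, smallest possible p 0.005). The Pearson and Spearman correlations of the KO effects at the 2 ages were set beside 100 regroupings.

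The other settings fixed in that plan were edgeR quasi-likelihood, DESeq2 and limma-voom on the recovered reads, trimmed-mean (TMM) scaling, no filter or a mean of at least 1 CPM (also 10 CPM for the correlation of effects), pseudocounts of 0.1 and 5 in place of 1, no batch term, only the groups compared, each batch alone, the replicate number as a block, and leaving out each library in turn. Alternatives that address the makeup of the libraries were chosen after seeing the data: 3 surrogate variables estimated by sva, 3 region-marker covariates (principal components that hold 95.9% of the variance of 8 regional lists), only the 11 forebrain-rich libraries, and only the 5 cerebellum-rich P25 libraries. Forebrain-rich libraries are those whose cerebellar granule list lies below its mean over all libraries and whose olfactory bulb list lies no more than 1 log2 unit above its mean. Cerebellum-rich libraries have a granule list more than 3 log2 units above its mean. Leaving out each library in the list tests was also added after seeing the data. Surrogate variables are estimated from the same values that are then tested, so their p-values are less sure than those of the fixed model.

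Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and sva 3.50.0. The procedure was tested on simulated data, with counts drawn for the real genes at the real library sizes. Both groups compared were given 1 common mean per gene, taken from the real data, before a set of genes was changed. For KO against WT, 58% (P14) and 55.2% (P25) of genes given a 2-fold change were called, and 86.6% and 81.6% of those given a 4-fold change. For P25 against P14 the shares were 58.3% (WT) and 46.9% (KO) at 2-fold, and 82.3% and 88.7% at 4-fold. Unchanged genes were called 9, 5, 3 and 6 times in the same order, among 18117, 18111, 18102 and 18084 genes. The simulation draws genes independently and does not carry variation that many genes share. Batch and group differences of the compared libraries were removed by the common mean, so the shares called need not hold for the real data.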

Results

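Shank2 encodes a scaffold protein of the postsynaptic density at excitatory synapses, and mutations of its human counterpart occur in autism spectrum disorder. The series profiled brain RNA of WT and Shank2 KO mice at P14 and P25, before and around weaning. Each of the 4 groups held 6 libraries (n = 6), of which the labels mark 3 as a second batch; the other 3 carry no batch mark and were taken as the first. Recovered read totals ran from 27552844 to 40787586 reads per library, and 24574 to 27475 genes had at least 1 read. All libraries carried the Y-linked transcript Ddx3y (values of 1424 to 2822) and little of the X-inactivation transcript Xist (0 to 13). Mitochondrially encoded genes took 3.01% to 4.62% of the reads, and the 10 most abundant genes took 4% to 7%. Values are deposited read counts after division by a size factor, and fold changes are on the log2(value + 1) scale with the standard error (SE) of limma.

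Marker genes of brain regions differed between libraries of the same group. Cbln3, a cerebellin made by cerebellar granule neurons, ran from 54064 to 61110 in the P25 WT libraries of the second batch and from 21 to 2373 in those of the first. In P25 KO libraries it ran from 30 to 56632 in the second batch and from 27 to 25147 in the first. At P14 it reached 6083 in WT replicate 3 and 10664 in KO replicate 1, against 18 to 52 in the other P14 libraries. Emx2, a transcription factor gene of the developing cortex, was at 0, 1 and 0 in P25 WT replicates 4, 5 and 6, at 4 and 0 in P25 KO replicates 5 and 6, and at 31 in P25 KO replicate 2. In the 11 forebrain-rich libraries Emx2 ran from 268 to 409. The list of olfactory bulb neurons and migrating neuroblasts stood 3.47, 3.93, 3.74 and 3.11 log2 units above its mean over all libraries in P14 WT replicate 5, P14 KO replicates 4 and 6 and P25 KO replicate 4. Striatal projection neuron genes stood 2.93 and 2.21 above theirs in P25 WT replicates 1 and 2. The pituitary list stood 7.43 above its mean in P25 WT replicate 3, where growth hormone (Gh) reached 72845. Choroid plexus genes stood 3.85 above their mean in P25 WT replicate 6, where the transthyretin gene Ttr reached 241250. The first principal component of the 24 libraries held 53.7% of the variance, and the next 3 held 13.4%, 10.4% and 4.5%.

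**Figure D1:**
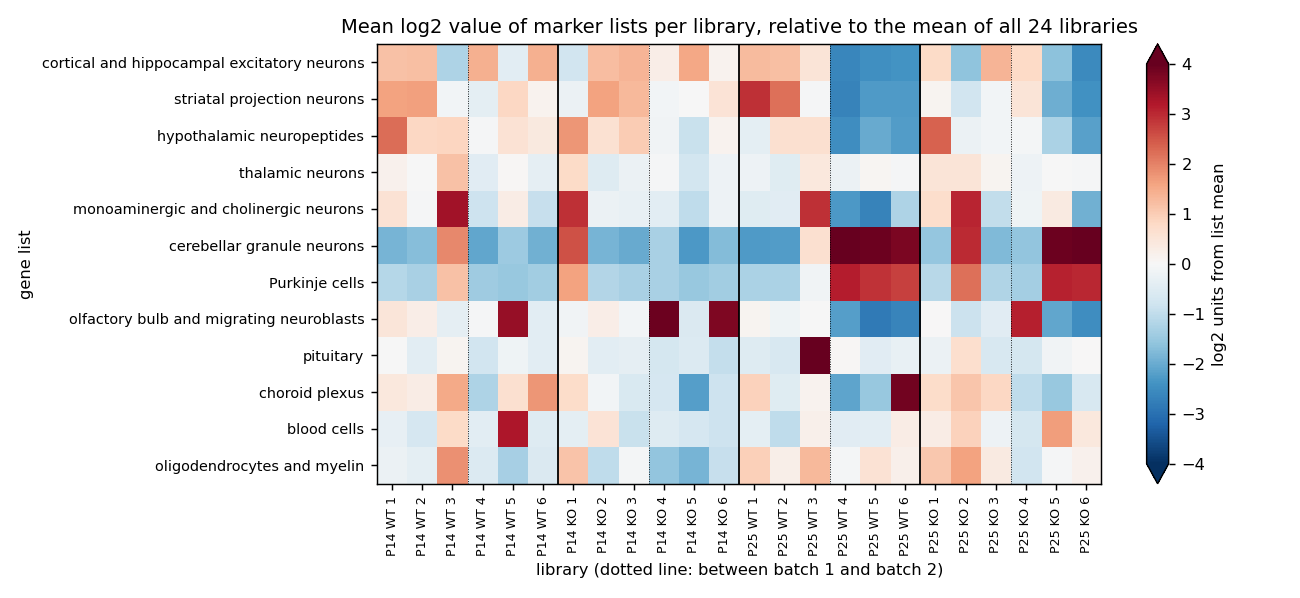
Heat map of 12 gene lists (vertical axis) in the 24 libraries (horizontal axis); colour is the mean log2 value of the list relative to its mean over all libraries. The granule neuron list stands at 3.76 to 4.01 in P25 WT replicates 4 to 6 and P25 KO replicates 5 and 6, and the pituitary list at 7.43 in P25 WT replicate 3.

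The targeted gene was measured first. Shank2 (ENSMUSG00000037541, GRCm38 chromosome 7, 144001928 to 144424494, plus strand) averaged 7937 ± 3440 in WT and 4068 ± 1461 in KO at P14 (SD, n = 6), so KO libraries held 51.3% of the WT mean. At P25 it averaged 9550 ± 2854 in WT and 3877 ± 1277 in KO (SD, n = 6), or 40.6%. Every P25 KO library (6 of 6) lay below every P25 WT library, and 3 of 6 P14 KO libraries lay below every P14 WT library. The lowest WT value at P14, 3932 in replicate 5, lay under the highest KO value of 6458. KO percentages of the WT mean were 48.3 and 53.5 in the first and second batch at P14, and 41.5 and 40.1 at P25. The log2 differences were −0.93 (SE 0.26) at P14 and −1.33 (SE 0.26) at P25. The 2-sided exact permutation test within batches gave p = 0.025 at P14 and p = 0.005 at P25, the smallest it can give. Adjusted over a family of 4 such tests by the Benjamini-Hochberg method these exact p were 0.025 and 0.00667. Across all genes limma gave adjusted p = 1 at P14 and 0.446 at P25. Without P14 WT replicate 5 the P25 difference passed (limma adjusted p = 0.0464). The labels do not say which exons were removed, so reads of kept exons count toward these values.

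**Figure D2:**
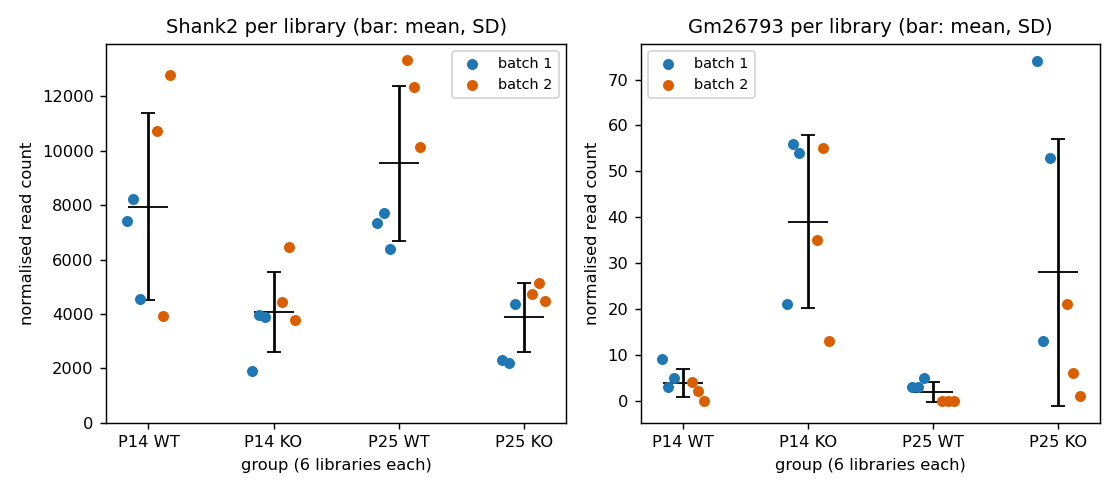
Deposited values of Shank2 and Gm26793 (vertical axes) for each library in the 4 groups, with points coloured by batch and bars for the mean and SD. Shank2 in P25 KO libraries runs from 2217 to 5153, under the 6382 to 13358 of the WT libraries, and Gm26793 is above every WT library in 6 of 6 P14 KO libraries.

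A noncoding gene near Shank2 had the smallest p at both ages. Gm26793 (ENSMUSG00000096999, GRCm38 chromosome 7, 144894560 to 144897461, minus strand, annotated as antisense) starts 470066 bases beyond the end of Shank2. Its values were 3.84 ± 3.06 in WT and 39.1 ± 18.9 in KO at P14 (SD, n = 6), and 1.81 ± 2.2 in WT and 27.9 ± 29 in KO at P25. The log2 differences were 3.18 (SE 0.56, 2.69 and 3.67 in the first and second batch) and 2.91 (SE 0.56, 3.08 and 2.73). At P14 6 of 6 KO libraries lay above every WT library, and at P25 5 of 6 did. The exact permutation p was 0.005 at each age (0.00667 over the 4 tests), for a gene picked because its p was small. Across all genes limma gave adjusted p of 0.247 and 0.446, and DESeq2 called the gene at both ages (adjusted p = 0.0122 and 0.00142). LTO1, a ribosome maturation factor gene at 144915100 to 144931701 on the same chromosome, had differences of 0.21 (SE 0.07) and 0.23 (SE 0.07), which did not pass. Cttn, the cortactin gene next to Shank2 and a partner of Shank proteins, had −0.04 (SE 0.08) and 0.10 (SE 0.08). The strand setting of the counting is not given in the sources used here, so reads of Gm26793 and of any transcript on the opposite strand cannot be told apart.

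**Figure D3:**
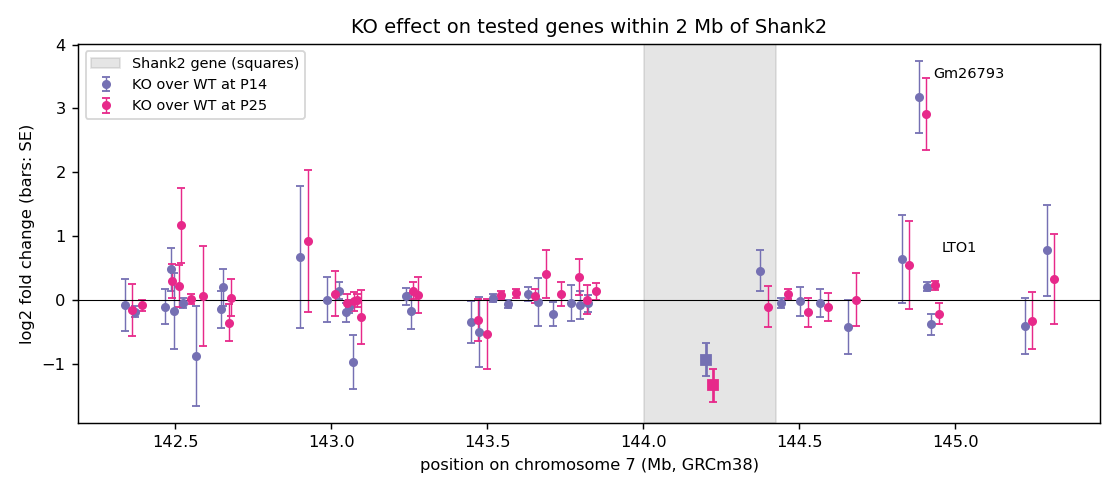
KO minus WT log2 differences (vertical axis, bars are SE) at P14 and P25 for tested genes within 2 Mb of Shank2, by position on chromosome 7 (horizontal axis, Mb). Gm26793 stands at 3.18 and 2.91 and Shank2 at −0.93 and −1.33.

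The comparison of KO and WT at P14 asks what the loss of Shank2 changes in the brain of preweaning mice. The differences that passed lay in gene groups, by camera alone. Their number does not exclude chance: 16 lists passed, against a median of 17 in other splits of the same libraries. Genes linked to autism stood higher in KO, while genes of the choroid plexus, which secretes cerebrospinal fluid, of myelinating oligodendrocytes and of mitochondrial respiration stood lower (each adjusted p = 0.714 with an estimated correlation). Single genes did not pass: limma called 0 of 18267, with 554 at an unadjusted p under 0.05. On the recovered reads edgeR called 0 (818 unadjusted), limma-voom 0 (567 unadjusted) and DESeq2 1, Gm26793 (1109 unadjusted). After Gm26793, the smallest p belonged to the ubiquitin-conjugating enzyme gene Ube2e3 (0.31, SE 0.07), Gramd4 (0.31, SE 0.07), Lrch2 (0.36, SE 0.09) and Gm38228 (0.82, SE 0.21), each with limma adjusted p = 1. The related scaffold genes Shank1 (0.21, SE 0.29) and Shank3 (0.02, SE 0.27) and the NMDA receptor subunit genes Grin1 (0.09, SE 0.21), Grin2a (0.06, SE 0.44) and Grin2b (0.35, SE 0.76) differed by less than their SE. Surrogate variables, added after seeing the data, let 2 genes pass, Shank2 (−1.17, adjusted p = 1.65e-07) and Gm26793 (3.28, adjusted p = 0.02).

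Of the 40 lists, camera called 16 at P14, 3 higher and 13 lower in KO, and 0 with an estimated correlation or with fry. No list had a member that passed on its own, over all genes or adjusted over the list alone (0 members). The 59 measured autism risk genes stood higher by a mean of 0.14 (camera adjusted p = 4.49e-11, adjusted p = 0.714 with an estimated correlation); Pogz, a chromatin regulator, had 0.18 (SE 0.07) and Rai1 0.20 (SE 0.09). The 16 AMPA receptor genes (mean 0.22, adjusted p = 0.0166) included the main subunits Gria1 (0.32, SE 0.19) and Gria2 (0.34, SE 0.23), and the 20 immature neuron genes (mean 0.21, adjusted p = 0.0166) included Crmp1 (0.34, SE 0.18) and Sox4 (0.53, SE 0.42); both lists had adjusted p = 0.714 with an estimated correlation. The 79 nuclear-encoded oxidative phosphorylation genes stood lower by a mean log2 of −0.10 (4.87e-13), with complex I subunits Ndufc1 (−0.15, SE 0.06) and Ndufb10 (−0.15, SE 0.06), and the 86 ribosomal protein genes also by −0.10 (4.36e-07), with Rps6 at −0.14 (SE 0.10) and Rps4l at −0.26 (SE 0.14). Each of these had adjusted p = 0.714 with an estimated correlation. Choroid plexus genes averaged −1.18 over 20 members (2.96e-07), with the ion channel gene Clic6 at −1.73 (SE 0.89) and Calml4 at −1.91 (SE 0.83). That list stood at 1.77 and 1.51 in P14 WT replicates 6 and 3 and at −2.19 in P14 KO replicate 5, and Ttr, not itself called, ran from 110 to 51401 across the P14 libraries. The 24 oligodendrocyte genes averaged −0.52 (1.24e-07), with the myelin cytoskeleton gene Ermn at −1 (SE 0.48). Both had adjusted p = 0.714 with an estimated correlation, and the myelin list stood at 1.82 above its mean in P14 WT replicate 3, the library with the highest cerebellar markers among P14 WT.

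Genes switched on by neuronal activity also stood lower at P14. The 25 immediate early genes averaged −0.17 (camera adjusted p = 0.0099, adjusted p = 0.714 with an estimated correlation), with Ier2 at −0.56 (SE 0.17) and the phosphatase gene Dusp1 at −0.40 (SE 0.17). Vessel-related lists were lower as well: 21 endothelial genes averaged −0.10 (0.00117), with the receptor genes Eng at −0.27 (SE 0.09) and Emcn at −0.41 (SE 0.16), and 21 mural and meningeal genes averaged −0.30 (0.00557), with pericyte markers Rgs5 at −0.44 (SE 0.15) and Pdgfrb at −0.22 (SE 0.11). Both had adjusted p = 0.714 with an estimated correlation. Blood cell genes averaged −0.80 (0.0003), ependymal genes −0.37 (0.0186), stress response genes −0.15 (0.00239), interferon-responsive genes −0.21 (0.00557) and thalamic genes −0.25 (0.0266); all had adjusted p = 0.714 with an estimated correlation. Proliferation genes averaged −0.22 (0.0166, adjusted p = 0.817 with an estimated correlation). Named members were Camp (−2.25, SE 1.00) and Hba-a2 (−0.55, SE 0.34) for blood, and Cfap126 (−0.92, SE 0.62) and Rarres2 (−0.37, SE 0.23) for ependyma. Ddit3 (−0.20, SE 0.14) and Dnajb9 (−0.13, SE 0.07) stand for stress, B2m (−0.17, SE 0.11) and Ifi44 (−0.51, SE 0.34) for interferon, Mcm6 (−0.24, SE 0.19) and Ccnb2 (−0.37, SE 0.32) for proliferation, and Tnnt1 (−1.05, SE 0.55) and Rgs16 (−0.38, SE 0.22) for thalamus. The blood list stood 3.23 above its mean in P14 WT replicate 5. NMDA receptor subunits (mean 0.07, adjusted p = 0.504) and postsynaptic scaffolds (mean 0.13, adjusted p = 0.158) did not pass, although the scaffold list passed in forebrain-rich libraries only (0.12, 0.00955) and with region covariates (0.20, 0.000113).

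Single libraries decided many of these list calls. Without P14 WT replicate 3 only 6 lists passed at P14, without P14 KO replicate 5 10, and without P14 WT replicate 5 12. The autism, choroid plexus and oxidative phosphorylation lists passed in all 24 fits that left out 1 library, but the autism mean of 0.14 fell to 0.05 without P14 WT replicate 5 and 0.07 without P14 WT replicate 3. Of the 16 means, 14 moved by over 1.5 times in at least 1 of these fits. In forebrain-rich libraries only, a choice made after seeing the data, the autism list was at 0.03 (adjusted p = 0.37) and the oxidative phosphorylation list at −0.01 (0.478), so both calls were lost, while the choroid plexus list was at −1.42 (1.97e-10). Among the 24 fits, the oligodendrocyte list was lost only without P14 WT replicate 3 (adjusted p = 0.053), and the blood (0.567) and ribosomal (0.579) lists only without P14 WT replicate 5. The blood and ribosomal lists were also lost in the first batch (−0.02, 0.8, and −0.01, 0.597) and in forebrain-rich libraries only (0.26, 0.171, and −0.01, 0.407). The endothelial list was lost without P14 WT replicate 3 (0.272), in the second batch (0.21), in forebrain-rich libraries only (mean 0, 0.495) and with surrogate variables (0.0924). The immature neuron list was lost without KO replicate 2 (0.162), WT replicate 3 (0.114) or WT replicate 6 (0.164), and the AMPA list without KO replicate 5 (0.0584), WT replicate 3 (0.114) or WT replicate 5 (0.436). The immature mean fell from 0.21 to 0.10 without WT replicate 6. The AMPA mean fell from 0.22 to 0.12 and 0.11 without WT replicates 3 and 5. In the other fits named for these lists the means moved by no more than 1.5 times. The immediate early list was lost without KO replicates 1 (0.32) or 5 (0.0649) or WT replicates 1 (0.12), 2 (0.0615) or 6 (0.0644). Its mean of −0.17 turned to 0.05 without KO replicate 1, and was −0.06, −0.06 and −0.10 without WT replicates 1, 2 and 6. Without KO replicate 5 it moved by no more than 1.5 times. The interferon list was lost without KO replicate 5 (0.181), WT replicate 3 (0.145) or WT replicate 5 (0.556). Its mean of −0.21 became −0.13 in each of the first 2 of these fits and turned to 0.06 without WT replicate 5. The mural list was lost without KO replicates 3 (0.0574) or 5 (0.157) or WT replicates 3 (0.114) or 5 (0.625), and the proliferation list without KO replicates 3 (0.0901) or 5 (0.75) or WT replicates 3 (0.102) or 5 (0.0531). Without WT replicate 5 the proliferation mean turned from −0.22 to 0.11 and the mural mean from −0.30 to 0.01. The stress list was lost without KO replicate 1 (0.0713), WT replicate 3 (0.0554) or WT replicate 5 (0.0768). The ependymal list was lost without KO replicates 3 (0.0574) or 5 (0.67) or WT replicates 1 (0.0557), 3 (0.0801) or 5 (0.607). Its mean of −0.37 fell to −0.10 without KO replicate 5 and −0.07 without WT replicate 5. In the other fits named it moved by no more than 1.5 times. The thalamic list was lost without KO replicates 2 (0.306), 3 (0.127) or 5 (0.181) or WT replicates 3 (0.444) or 5 (0.0554). In both batches taken alone, 5 lists passed: autism risk, choroid plexus, immediate early, oxidative phosphorylation and oligodendrocytes; 15 of 16 had the same direction in both. Taking each batch alone, forebrain-rich libraries only, surrogate variables and region covariates together, 3 of the 16 lists passed throughout in the same direction: choroid plexus, immediate early genes and oligodendrocytes.

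At P25, lists of hypothalamic neuropeptides and of blood cells stood higher in KO and mitochondrially encoded genes lower by camera (adjusted p = 0.478, 0.608 and 0.478 with an estimated correlation). Shank2 was the protein-coding gene with the smallest p. Hcrt, the precursor of the wake-promoting orexins, had a difference of 2.63 (SE 1.13) and Cartpt, the precursor of an appetite-regulating peptide, 2.12 (SE 0.89, −0.10 and 4.34 in the first and second batch). Single genes again did not pass in limma: 0 of 18267, with 98 at an unadjusted p under 0.05. EdgeR called 0 (172 unadjusted), limma-voom 0 (106 unadjusted) and DESeq2 5 (484 unadjusted), which were Shank2, Gm26793, Hcrt, the olfactory calcium-binding protein gene S100a5 and the repeat-rich Gm10800. After Gm26793 and Shank2, the smallest p belonged to Rps16-ps2 (0.79, SE 0.23), LTO1 and the DNA repair gene Fancb (−0.52, SE 0.16), with limma adjusted p = 1. Rps16-ps2 is a pseudogene that shares sequence with Rps16, so its count is uncertain. Shank1 (0.10, SE 0.29), Shank3 (−0.23, SE 0.27), Grin1 (−0.11, SE 0.21), Grin2a (−0.02, SE 0.44) and Grin2b (0.45, SE 0.76, −0.95 and 1.85 by batch) did not pass. Surrogate variables and region covariates, added after seeing the data, each let 1 gene pass, Shank2 (−1.22, adjusted p = 7.88e-08, and −1.13, adjusted p = 0.0397).

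Camera called 22 lists at P25, 13 higher and 9 lower in KO, and 0 with an estimated correlation or with fry. In these lists 0 members passed over all genes or adjusted over the list alone. Other splits of the same libraries gave a median of 16 lists. The 14 hypothalamic neuropeptide genes averaged 0.71 (camera adjusted p = 9.4e-05, adjusted p = 0.478 with an estimated correlation). The 13 blood cell genes averaged 0.70 (9.83e-05, adjusted p = 0.608 with an estimated correlation), with the granulocyte genes S100a8 at 1.82 (SE 1.03) and S100a9 at 1.97 (SE 1.12). The 12 mitochondrially encoded genes averaged −0.14 (1.83e-06, adjusted p = 0.478 with an estimated correlation), with mt-Co3 at −0.50 (SE 0.20) and mt-Atp6 at −0.30 (SE 0.15). Those members averaged only 2.73 and 7.9 CPM and share sequence with nuclear copies, so their counts are uncertain. Glucocorticoid-responsive genes averaged −0.19 over 19 members (6.28e-06, adjusted p = 0.478 with an estimated correlation), with Map3k6 at −0.52 (SE 0.26) and the metabolic kinase gene Pdk4 at −0.25 (SE 0.14); among the 24 fits that left out 1 library the list was lost without P25 KO replicate 6 (0.0963), and it was also lost in the first batch (−0.04, 0.752) and in forebrain-rich libraries only (0.07, 0.965). The 8 pituitary genes averaged −1.11 (0.000248, adjusted p = 0.579 with an estimated correlation), with hormone subunit genes Fshb (−1.47, SE 1.01) and Cga (−1.53, SE 1.17). That list could not be tested without P25 WT replicate 3, which alone holds it far above its mean. The blood, hypothalamic and mitochondrial lists passed in all 24 fits that left out 1 library, but the hypothalamic mean fell to 0.37 without P25 KO replicate 1 and 0.43 without P25 KO replicate 4, and the blood mean to 0.44 without P25 KO replicate 5. Of the 22 means, 19 moved by over 1.5 times in at least 1 of these fits. Other settings ended these calls: the hypothalamic list was at 0.36 with surrogate variables (0.0756), 0.26 with region covariates (0.19) 0.41 in the first batch (0.193) and 0.06 in cerebellum-rich libraries only (0.918). The blood list was at 0.40 in forebrain-rich libraries only (0.335) and the mitochondrial list at −0.06 in the second batch (0.323).

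Lists that follow brain regions went apart between the batches at P25. The 16 striatal projection neuron genes averaged −0.43 (camera adjusted p = 2.25e-05, adjusted p = 0.608 with an estimated correlation), at −1.96 in the first batch and 1.11 in the second. Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, had −1.22 (SE 0.59) and Syndig1l −1.20 (SE 0.56), and the list was lost without P25 WT replicate 1 (0.274) or P25 KO replicate 2 (0.0806). The striatal mean was 0.02 without P25 WT replicate 1 and −0.14 without P25 KO replicate 2 or P25 WT replicate 2. Without P25 KO replicate 4 it was −0.99. In P25 WT replicates 1 and 2 the striatal list stood 2.93 and 2.21 above its mean. Purkinje genes averaged −0.25 (0.0421, adjusted p = 0.761 with an estimated correlation), with 0.84 and −1.35 by batch; members were Pcp4 (−0.43, SE 0.25) and Calb1 (−0.31, SE 0.58). The Purkinje list passed in 16 of 24 fits that left out 1 library (highest adjusted p 0.45 without WT replicate 4), and without KO replicate 4 it passed in the other direction (0.000579). In the second batch the granule neuron list stood at 3.76 to 4.01 in 3 WT and 2 KO libraries and at −1.57 in KO replicate 4. Olfactory bulb genes averaged 0.84 (0.000169, −0.45 and 2.08), with Trh (1.48, SE 0.95) and Tbx21 (1.63, SE 1.43), ribosomal genes 0.09 (1.3e-11, −0.02 and 0.19), with Rps15a (0.14, SE 0.08) and Rpl22l1 (0.17, SE 0.10); both had adjusted p = 0.643 with an estimated correlation. Immature neuron genes averaged 0.34 (6.28e-06, −0.01 and 0.69, adjusted p = 0.5 with an estimated correlation), with Cd24a (0.78, SE 0.45) and Dpysl5 (0.36, SE 0.26). Proliferation genes averaged 0.24 (0.000279, −0.01 and 0.49, adjusted p = 0.663 with an estimated correlation), with Mki67 (0.88, SE 0.51) and Aurkb (0.61, SE 0.43). Without P25 KO replicate 4, whose olfactory bulb list stood at 3.11, these 4 lists were lost (olfactory bulb 0.653, ribosomal 0.21, immature 0.94, proliferation 0.229) and 14 lists passed. The olfactory bulb and ribosomal means then changed sign, to −0.10 and −0.02, and the immature and proliferation means fell to 0.02 and 0.09.

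The remaining lists called at P25 covered transmitter systems, glia, vessels and metabolism, and each was lost in at least 2 of the 24 fits that left out 1 library. Monoaminergic and cholinergic genes averaged 0.88 (camera adjusted p = 0.00105, adjusted p = 0.608 with an estimated correlation), with the dopamine transporter gene Slc6a3 at 3.39 (SE 1.46) and Dbh at 1.25 (SE 1.08); the list was lost without KO replicates 2 (0.299), 4 (0.0734) or 5 (0.0542) and stood at 2.93 in P25 WT replicate 3 and 3.06 in P25 KO replicate 2. Thalamic genes averaged 0.22 (0.0221, adjusted p = 0.608 with an estimated correlation, passed in 19 of 24 such fits, highest 0.408 without WT replicate 2), with Slc17a6 (1.00, SE 0.62) and Tnnt1 (0.80, SE 0.55). Microglial genes averaged 0.13 (0.0182, −0.36 and 0.61 by batch, adjusted p = 0.761 with an estimated correlation, lost without KO replicate 3, 0.145, or WT replicates 4, 0.57, 5, 0.0557, and 6, 0.22), with Ptprc (0.34, SE 0.26) and Aif1 (0.30, SE 0.35). Without KO replicate 4 the microglial list passed in the other direction (3.18e-08). Interferon-responsive genes averaged 0.14 (0.0197, 18 of 24, highest 0.59 without KO replicate 2), stress genes 0.06 (0.0495, 11 of 24, highest 0.953 without KO replicate 3) and choroid plexus genes −0.21 (0.0415, 18 of 24, highest 0.56 without KO replicate 5), each with adjusted p = 0.761 with an estimated correlation. Without WT replicate 6 the choroid plexus list passed in the other direction (1.01e-10). Rtp4 (0.47, SE 0.27), Chac1 (0.43, SE 0.14) and Lbp (−0.77, SE 0.50) are members. Endothelial genes averaged −0.04 (0.0196, 19 of 24, highest 0.495 without WT replicate 3) and mural genes −0.13 (0.00136, without WT replicates 3, 0.248, or 6, 0.22), both with adjusted p = 0.643 with an estimated correlation, with Robo4 (−0.27, SE 0.10) and Slc13a4 (−0.51, SE 0.33). Cholesterol biosynthesis genes averaged 0.08 (0.00597, adjusted p = 0.663 with an estimated correlation, 18 of 24, highest 0.34 without KO replicate 2), with Fdft1 (0.20, SE 0.16) and Sqle (0.16, SE 0.13). Nuclear noncoding RNAs averaged 0.16 (0.0417, adjusted p = 0.478 with an estimated correlation, 17 of 24, highest 0.238 without KO replicate 2), with Miat (0.91, SE 0.65) and Gm26917 (0.52, SE 0.24). Oligodendrocyte genes averaged −0.13 (0.0486, adjusted p = 0.81 with an estimated correlation, 13 of 24, highest 0.819 without WT replicate 5), with Car2 (−0.12, SE 0.17) and Enpp2 (−0.48, SE 0.66). Of the 22 lists, 10 had the same direction in both batches and 1, blood cells, passed in each. Across both batches, forebrain-rich libraries only, surrogate variables and region covariates, 0 of the 22 camera calls passed throughout, and 6 passed in the other direction somewhere. These 6 were the choroid plexus (0.70, 3.83e-07), Purkinje (0.84, 0.00539) and microglial lists (−0.36, 6.71e-07) in the first batch, the striatal list in the second (1.11, 0.000264), and the mural (0.23, 0.0269), olfactory bulb (−0.22, 0.0191) and again microglial lists (−0.10, 0.0279) in forebrain-rich libraries only. In cerebellum-rich P25 libraries only, also chosen after seeing the data, 24 lists passed, 15 higher and 9 lower; 10 of the 22 calls passed there in the same direction and 2 in the other, Purkinje (0.12, 0.00882) and stress (−0.09, 0.0166).

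The design crosses genotype with age, and the difference between the KO effects at P25 and P14 was tested directly. Hypothalamic neuropeptides and blood genes had a higher KO effect at P25 than at P14, and autism risk and mitochondrially encoded genes a lower one, by camera (adjusted p = 0.56, 0.56, 0.56 and 0.646 with an estimated correlation). No gene passed in limma (0 of 18267, 189 unadjusted), edgeR (0, 258 unadjusted) or limma-voom (0, 187 unadjusted), and DESeq2 called 1, S100a5 (505 unadjusted). The smallest p belonged to the thalamic transcription factor gene Gbx2 (2.98, SE 0.78), the intermediate filament gene Prph (3.08, SE 0.89), Gm6592 (−1.01, SE 0.31), the potassium channel gene Kcns3 (1.58, SE 0.49) and the mitochondrial RNA-binding protein gene Ptcd1 (−0.30, SE 0.09), all with limma adjusted p = 1. Camera called 20 lists, 16 higher and 4 lower, and 0 with an estimated correlation or with fry; 0 members passed over all genes or adjusted over the list alone. Hypothalamic genes differed by 1.10 (camera adjusted p = 0.000118), with Gal (2.14, SE 0.88) and Hcrt (2.99, SE 1.59), blood genes by 1.50 (2.22e-08), with Camp (3.10, SE 1.41), thalamic genes by 0.48 (0.000882), with Tnnt1 (1.85, SE 0.78) and Slc17a6 (1.66, SE 0.88), and autism risk genes by −0.12 (2.2e-08), with Pogz (−0.17, SE 0.10) and Ash1l (−0.24, SE 0.14). Each of these 4 lists had adjusted p = 0.56 with an estimated correlation. Ribosomal (mean 0.18, adjusted p = 1.43e-17, Rpl14 0.32, SE 0.16), oxidative phosphorylation (mean 0.09, adjusted p = 1.82e-09, Ndufb10 0.17, SE 0.09) and stress response genes (mean 0.21, adjusted p = 8.92e-05, Chac1 0.47, SE 0.20) were higher, each with adjusted p = 0.712 with an estimated correlation, and mitochondrially encoded genes lower (mean −0.23, adjusted p = 2.16e-05, mt-Co3 −0.77, SE 0.28, adjusted p = 0.646 with an estimated correlation). These 8 lists passed in all 24 fits that left out 1 library, yet single libraries moved 5 of their means by over 1.5 times. Without P14 WT replicate 5 the blood mean fell to 0.73, the autism mean to −0.04, the ribosomal mean to 0.11 and the stress mean to 0.12. Without P25 KO replicate 4 the ribosomal mean was 0.08, the stress mean 0.12 and the autism mean −0.19. The autism mean was −0.05 without P14 WT replicate 3 or P25 KO replicate 2, and the thalamic mean 0.30 without P14 WT replicate 3. In forebrain-rich libraries only, the blood (0.14, adjusted p = 0.995), autism (−0.08, 0.473) and oxidative phosphorylation lists (−0.02, 0.581) were lost, the last with its sign changed. The hypothalamic list was lost with surrogate variables (0.45, 0.379) and region covariates (0.42, 0.0679), the ribosomal list in the first batch (−0.01, 0.897), and the thalamic (0.05, 0.895) and mitochondrial lists (−0.17, 0.118) in the second.

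The other 12 lists called for this difference, among them glia, choroid plexus and dividing cells, were each lost in at least 1 of the 24 fits that left out 1 library. Interferon-responsive genes (mean 0.35, adjusted p = 8.92e-05) and proliferation genes (mean 0.45, adjusted p = 1.66e-05) were lost among these fits only without P14 WT replicate 5 (0.301 and 0.404). Both were also lost in the first batch (0.15, 0.0799, and −0.07, 0.364), in forebrain-rich libraries only (−0.02, 0.906, and 0.07, 0.532) and with surrogate variables (0.13, 0.205, and 0.13, 0.236). Members were Ifi44 (1.00, SE 0.47), Isg15 (0.81, SE 0.48), Mki67 (1.21, SE 0.73) and Mcm6 (0.46, SE 0.27). Choroid plexus genes (mean 0.97, adjusted p = 0.00242, Calml4 1.78, SE 1.18) were lost without P14 KO replicate 5 (0.0696), P14 WT replicate 6 (0.123) or P25 WT replicate 4 (0.147). Oligodendrocyte genes (mean 0.39, adjusted p = 0.00105, Ermn 0.91, SE 0.68) were lost without P14 KO replicate 2 (0.188), P14 WT replicate 3 (0.592), P25 KO replicate 2 (0.183) or P25 WT replicate 2 (0.0827). Monoaminergic genes (mean 1.15, adjusted p = 0.00469, Slc6a3 3.10, SE 2.06) were lost without P14 KO replicate 2 (0.0562), P14 WT replicate 3 (0.154) or P25 KO replicate 2 (0.166). Striatal (mean −0.32, adjusted p = 0.0183, Syndig1l −1.53, SE 0.79, 14 of 24, highest 0.553 without P25 WT replicate 1), ependymal (mean 0.51, adjusted p = 0.013, Ccdc153 1.44, SE 1.08, 18 of 24, highest 0.328 without P14 KO replicate 5), glucocorticoid (mean −0.19, adjusted p = 0.0145, Hif3a −0.68, SE 0.47, 18 of 24, highest 0.359 without P25 KO replicate 6) and immediate early genes (mean 0.25, adjusted p = 0.0308, Ier2 0.53, SE 0.24, 14 of 24, highest 0.926 without P25 KO replicate 4) passed in fewer of the fits. So did cholesterol genes (mean 0.10, adjusted p = 0.0323, Pmvk 0.17, SE 0.11, 12 of 24, highest 0.675 without P14 WT replicate 3) and the chromosome 7 neighbours of Shank2 (mean 0.09, adjusted p = 0.0451, Cars 0.17, SE 0.10, 11 of 24, highest 0.65 without P14 WT replicate 5). All of these had adjusted p = 0.712 with an estimated correlation. The immediate early mean turned to −0.15 without P25 KO replicate 4 and the striatal mean to 0.13 without P25 WT replicate 1. Without P14 WT replicate 5 the chromosome 7 mean turned to −0.06. Microglial genes (mean 0.19, adjusted p = 0.0368, Ptprc 0.59, SE 0.37, adjusted p = 0.808 with an estimated correlation) passed in 13 of 24 fits (highest 0.614 without P14 KO replicate 1) and passed in the other direction without P25 KO replicate 4 (0.0117), in the first batch (−0.25, 0.00526) and in forebrain-rich libraries only (−0.18, 0.00221), where the cholesterol list did so too (−0.17, 0.0359). Of the 20 lists, 1, stress response genes, passed throughout across both batches, forebrain-rich libraries only, surrogate variables and region covariates.

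The KO effects at P14 and P25 were compared across genes, and the sign of their correlation depended on the setting. Pearson's r over the 18267 genes was 0.08 and Spearman's rho 0.11, and genes are not independent replicates. Among 100 regroupings, the real one included, 75 gave an r as far from 0, and the others ran from −0.67 to 0.63 (SD 0.31). Under other settings r was 0.27 (rho 0.32) with region covariates, 0.17 at a mean of at least 10 CPM, −0.15 in the first batch, 0.12 in the second and −0.20 in forebrain-rich libraries only. The effects in the first and second batch had r = 0.17 at P14 and −0.60 at P25. A genotype by batch term passed for 0 genes at P14 in limma (250 unadjusted), edgeR (484) and limma-voom (245), and for 0 at P25 (529, 1204 and 516).

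From P14 to P25 the WT brain libraries lost transcripts of immature neurons, dividing cells, oligodendrocyte precursors and ribosomes and gained transcripts of myelin by camera, lists for which an estimated correlation gave adjusted p of 0.707 to 0.908. Limma called 5134 of 18267 genes, 2498 up and 2636 down. The collapsin response mediator gene Dpysl5 fell by 2.12 on the log2 scale (SE 0.26), from 7561 ± 2235 to 1696 ± 419 (SD, n = 6), and the actin regulator gene Marcksl1 fell by 2.45 (SE 0.33). Plk5, a kinase-related gene of differentiated neurons and glia, rose by 3.06 (SE 0.57, 1.16 and 4.96 in the first and second batch). Klk6, a protease gene of mature oligodendrocytes, rose by 3.69 (SE 1.11, 2.33 and 5.05), and Prph, which encodes peripherin, fell by 3.94 (SE 0.63, −2.08 and −5.79). Of 5037 called genes measured in both batches, 4360 (86.6%) had the same sign in each, with a median size of 0.26 in the first and 0.91 in the second. These genes were picked in the fit of both batches, which favours a shared sign. Over all 17541 genes measured in both, the age effects of the batches had r = −0.09 (Spearman's rho 0.06). In the second batch all P25 WT libraries were cerebellum-rich and all P14 WT libraries had Cbln3 of 19 to 30. Taken alone, the first batch called 53 genes and the second 6163. Among the forebrain-rich libraries, a choice made after seeing the data, 2318 genes passed, of which 1158 were among the 5134.

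The largest rises and falls in WT were mostly larger in the second batch. Beside Klk6 and Plk5 the rises were Hes3 (4.52, SE 1.52, 0.51 and 8.52 by batch), a repressor of neural progenitors, A930017K11Rik (4.12, SE 1.09, 0.92 and 7.31), Gm43065 (3.85, SE 1.12, 0.50 and 7.19), Vwa7 (3.46, SE 1.05, 0.53 and 6.39), Exph5 (2.93, SE 0.57, 1.42 and 4.44), the potassium channel gene Kcng4 (2.91, SE 0.96, 0.43 and 5.38), the calcium buffer gene Pvalb of fast-spiking and Purkinje neurons (2.88, SE 1.01, 0.28 and 5.49) and Gm14033 (2.69, SE 0.79, 0.07 and 5.31). The largest falls beside Prph were Cbln2 (−3.94, SE 0.90, −0.29 and −7.58), the hippocampus-enriched receptor subunit gene Gabra5 (−3.86, SE 0.88, −0.06 and −7.66), the cortical layer 6 marker Ntsr1 (−3.81, SE 0.88, −0.03 and −7.59) and the stress peptide gene Crh (−3.59, SE 0.79, −0.56 and −6.62). Further ones were AW551984 (−3.73, SE 0.82), Dgkk (−3.73, SE 0.73), Igfbpl1 (−3.73, SE 1.32), Crabp1 (−3.66, SE 1.23) and the peptide gene Grp (−3.61, SE 0.95). Limma adjusted p ran from 0.000479 (Prph) to 0.0418 (Igfbpl1). Hes3 (highest adjusted p 0.0747), Kcng4 (0.0702), Pvalb (0.0916), Igfbpl1 (0.103) and Crabp1 (0.0758) failed in 7 to 9 of the 24 fits that left out 1 library, and Klk6 failed without P14 WT replicate 1 (0.0508) or 2 (0.0507). The libraries whose absence ended these calls were P14 WT replicates 1 to 5 and P25 WT replicates 2 to 6. With surrogate variables Klk6 (3.37, adjusted p = 0.00354), Plk5 (1.65, 0.0117) and Prph (−3.05, 0.017) still passed, as they did in forebrain-rich libraries only (3.55, 0.00375, 2.50, 0.000445, −2.84, 0.0138).

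**Figure D4:**
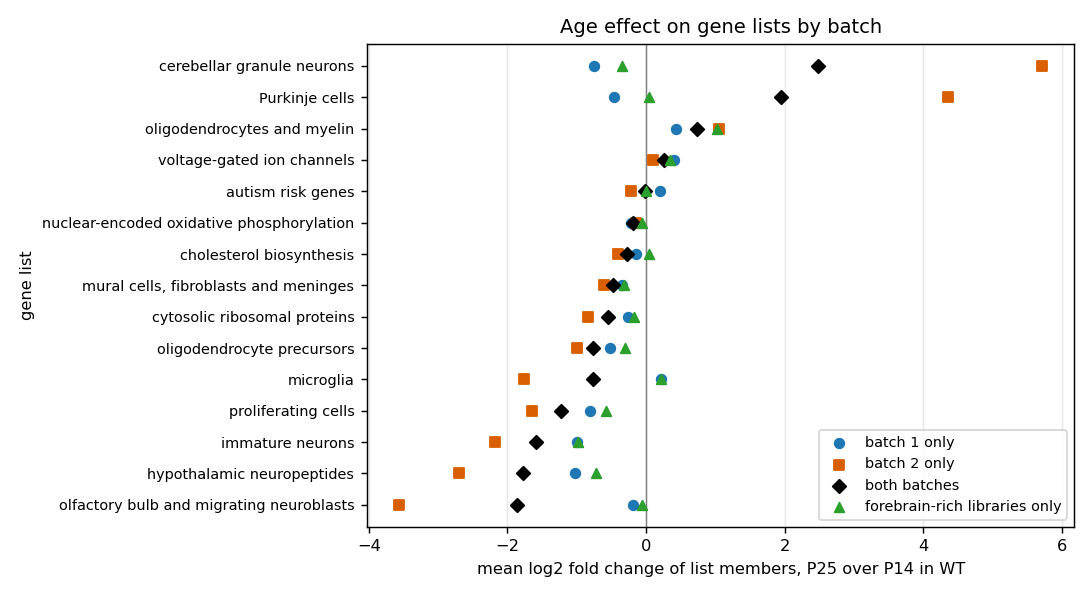
Mean log2 difference P25 minus P14 in WT (horizontal axis) of the 15 lists that passed (vertical axis), for both batches together, each batch alone and the forebrain-rich libraries only. Granule neuron genes stand at −0.75 in the first batch and 5.72 in the second, and immature neuron genes at −1 and −2.18.

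Camera called 15 of 40 lists for age in WT, 5 higher and 10 lower at P25. With an estimated correlation 0 held (smallest adjusted p 0.707), and fry called 6, all lower. Other splits of the same libraries gave a median of 18 lists by camera. Ribosomal protein genes averaged −0.55, with −0.26 and −0.83 in the first and second batch, −0.17 in forebrain-rich libraries only and −0.18 with surrogate variables. Of the 86, 80 fell (83 adjusted over the list alone), among them Rplp0 (−0.88, SE 0.11), Rpsa (−0.95, SE 0.13) and Rps24 (−0.85, SE 0.13), with camera adjusted p = 7.77e-28 (adjusted p = 0.753 with an estimated correlation). Ribosomal genes have many pseudogenes that share their reads. Of 20 immature neuron genes 17 fell (19 adjusted over the list alone, mean −1.59, camera adjusted p = 9.13e-10, adjusted p = 0.707 with an estimated correlation), with Tmsb10 at −1.40 (SE 0.20) beside Dpysl5 and Marcksl1. Of 23 proliferation genes 15 fell (18 adjusted over the list alone, mean −1.23, camera adjusted p = 1.26e-07, adjusted p = 0.908 with an estimated correlation), such as the DNA replication genes Rrm2 (−1.51, SE 0.25) and Mcm6 (−1.09, SE 0.19) and the mitotic gene Birc5 (−1.89, SE 0.35). Of 15 oligodendrocyte precursor genes 10 fell (10 adjusted over the list alone, mean −0.76, camera adjusted p = 1.45e-05, adjusted p = 0.753 with an estimated correlation): Cspg4 (−0.96, SE 0.16) and Pdgfra (−1.08, SE 0.22), which mark precursors, and Gpr17 (−1.38, SE 0.25), which marks cells about to mature. Of 23 cholesterol biosynthesis genes 10 fell (11 adjusted over the list alone, mean −0.27, camera adjusted p = 0.00441, adjusted p = 0.908 with an estimated correlation), with Acat2 (−0.67, SE 0.13), Mvk (−0.53, SE 0.12) and Sqle (−0.61, SE 0.13). These 5 lists passed in each batch alone and in all 24 fits that left out 1 library. In forebrain-rich libraries only the cholesterol list was lost (0.04, 0.914), while the other 4 passed there, with surrogate variables and with region covariates. Oligodendrocyte and myelin genes averaged 0.74, with 5 of 24 risen (2 adjusted over the list alone, camera adjusted p = 0.00167, adjusted p = 0.908 with an estimated correlation): the carbonic anhydrase gene Car2 (0.68, SE 0.17), Sept4 (1.64, SE 0.47) and Plekhh1 (1.24, SE 0.41). Of 79 oxidative phosphorylation genes 40 fell and 1 rose (46 and 1 adjusted over the list alone, mean −0.18, camera adjusted p = 5.36e-07, adjusted p = 0.908 with an estimated correlation), with Cox7a2l (−0.49, SE 0.09), Sdhb (−0.38, SE 0.07) and Ndufc1 (−0.33, SE 0.06). That call was lost in the second batch (−0.15, 0.0592) and in forebrain-rich libraries only (−0.05, 0.109), and the myelin call in the first batch (0.43, 0.103). Plekhh1 failed without P14 WT replicates 1 (0.0765) or 2 (0.0795) or P25 WT replicates 3 (0.0642), 4 (0.0518) or 5 (0.0765).

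Lists of regional neurons, microglia and vessels differed in size or direction between the batches. Granule neuron genes averaged 2.49 (−0.75 and 5.72 by batch), with 3 of 14 risen (3 adjusted over the list alone): Tiam1 (0.96, SE 0.19), Car4 (1.37, SE 0.42) and Etv1 (1.14, SE 0.36). Camera gave adjusted p = 0.000623, and adjusted p = 0.908 with an estimated correlation. Purkinje genes averaged 1.95 (−0.46 and 4.36), with 5 of 16 risen (12 adjusted over the list alone, camera adjusted p = 0.000138, adjusted p = 0.908 with an estimated correlation), such as the calcium channel gene Itpr1 (2.47, SE 0.57), Rgs8 (2.18, SE 0.64) and Icmt (1.48, SE 0.43). Microglial genes averaged −0.77 (0.22 and −1.76), with 12 of 23 fallen (17 adjusted over the list alone, camera adjusted p = 1.51e-05, adjusted p = 0.908 with an estimated correlation), including Tyrobp (−0.87, SE 0.24), Laptm5 (−0.99, SE 0.28) and Fcrls (−1.22, SE 0.36). The microglial list passed upward in the first batch (0.22, 0.0471) and in forebrain-rich libraries only (0.21, 0.00112). In forebrain-rich libraries only the granule (−0.35, 0.491), Purkinje (0.05, 0.414), hypothalamic (−0.72, 0.241) and olfactory bulb calls (−0.05, 0.914) were lost, and with surrogate variables the olfactory bulb list passed upward (1.19, 0.0131). Hypothalamic peptide genes averaged −1.78, with 7 of 14 fallen (7 adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.908 with an estimated correlation, lost without P14 WT replicate 5, 0.0578, or P25 WT replicate 1, 0.0527), such as Cartpt (−3.95, SE 0.89) and Nts (−2.32, SE 0.62). Over the 24 fits that left out 1 library the hypothalamic mean ran from −1.91 to −1.59. Olfactory bulb genes averaged −1.86, with 4 of 16 fallen (4 adjusted over the list alone, camera adjusted p = 0.0332, adjusted p = 0.908 with an estimated correlation), such as Dcx (−2.31, SE 0.64), Trh (−3.24, SE 0.95) and Sall3 (−2.30, SE 0.81). That list was lost without P14 WT replicates 1 (0.0523), 3 (0.0537) or 5 (0.183) or P25 WT replicate 5 (0.0519), and its mean ran from −2.26 to −1.40 over the 24 fits. Mural genes averaged −0.47, with 4 of 21 fallen (4 adjusted over the list alone, camera adjusted p = 0.0426, adjusted p = 0.908 with an estimated correlation): Rgs5 (−0.82, SE 0.15), Pdgfrb (−0.34, SE 0.11) and Kcnj8 (−0.47, SE 0.15) are named. It was lost without P14 WT replicates 3 (0.142) or 5 (0.183), P25 WT replicates 1 (0.185), 2 (0.0688), 4 (0.0705) or 5 (0.0541), or P25 KO replicates 2 (0.0563) or 4 (0.0758). Car4, Pdgfrb, Etv1 and Kcnj8 failed without P25 WT replicate 4 (0.0559, 0.0591, 0.0584 and 0.0655) or 5 (0.0546, 0.0668, 0.0648 and 0.0561). Etv1 also failed without P14 WT replicates 1 (0.0501) or 5 (0.0564), Kcnj8 without P14 WT replicate 3 (0.0542) or P25 WT replicate 2 (0.0601), and Sall3 without any of 8 WT libraries (0.0548 to 0.0938).

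Ion channel and autism risk lists passed upward by camera with members going both ways (adjusted p = 0.908 with an estimated correlation). Of 25 voltage-gated channel genes 8 rose and 3 fell (11 and 3 adjusted over the list alone, mean 0.26, camera adjusted p = 0.0106, adjusted p = 0.908 with an estimated correlation). The fast-spiking channel gene Kcnc1 rose by 1.62 (SE 0.36) and the axonal channel gene Kcna2 by 0.87 (SE 0.22), while Scn3a, a sodium channel of the embryonic brain, fell by 2.34 (SE 0.57, 0.03 and −4.71 by batch). Of 59 autism risk genes 22 rose and 5 fell (24 and 6 adjusted over the list alone, camera adjusted p = 0.00441, adjusted p = 0.908 with an estimated correlation), with the chromatin genes Kmt2a (0.73, SE 0.11), Chd8 (0.37, SE 0.06) and Ash1l (0.58, SE 0.10). The mean of this list was −0.01 while its median (0.17) and its test pointed up, and it went apart between batches, at 0.20 in the first (0.000657) and −0.21 in the second (0.194). In forebrain-rich libraries only its mean was 0 (0.86). Without P14 WT replicate 5 both lists were lost (0.106 and 0.0737).

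In KO the age comparison called 2163 genes, 1077 up and 1086 down in limma. Of 2135 measured in both batches, 2131 (99.8%) had the same sign in each, with median sizes of 0.44 and 0.63. These too were picked in the fit of both batches. Over all 17541 genes the effects of the batches had r = 0.50 (rho 0.52). Genes called in both genotypes numbered 1881, and all 1881 had the same sign, while independent lists of these lengths would share 608. In the second batch P25 WT replicates 4 to 6 and P25 KO replicates 5 and 6 were cerebellum-rich, and Cbln3 was at most 52 at P14. The age comparisons share this difference and 1 fit, so the excess over 608 cannot be told apart from it. The first batch alone called 45 genes. In the second alone limma called 0 (4754 unadjusted), where P25 KO libraries held Cbln3 values of 30 to 56632. The count rested on single libraries. It rose to 6858 without P25 KO replicate 4, the P25 library of that batch with few cerebellar transcripts. It fell to 812, 848, 928 and 1212 without P25 KO replicates 5, 2, 6 and 3, and to 825 and 1253 without P14 KO replicates 2 and 3. The WT count fell to 3289 and 3402 without P25 WT replicates 5 and 4. Whether the age effect differs between genotypes is the same test as the difference of KO effects between ages, for which limma called 0 genes (189 unadjusted), edgeR 0 (258), limma-voom 0 (187) and DESeq2 1.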

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

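The tests of bone and olfactory mucosa transcripts and of other splits of the libraries were written down before their results were seen, while the tests against genotype, age or batch, sequencing depth, blood, a local effect at Shank2 and regional makeup at Shank2 were chosen after seeing the results they bear on, and the genes in the test of forebrain transcription factors were picked after the pattern was seen and shortened to 3 after their values were. In 56 of 475 groups of 6 libraries the highest or lowest library lay far from the other 5 by Dixon's criterion, and chance gives about 1 in 20 such groups, or 24 here. P14 WT replicate 3 stood apart in 16 of them: Ermn 4224, Rgs16 574, Dpysl5 3651, Slc17a6 6799, Cttn 4224, Hes3 295, Gm43065 7.88, Klk6 475, Vwa7 192, Kcng4 1622, Plekhh1 2407, Icmt 4159 and Kcnc1 10163, and list means of 1.92 for granule neurons, 1.18 for Purkinje cells and 3.36 for monoaminergic and cholinergic neurons. P14 WT replicate 5 did so in 12: Sox4 1288, Rgs5 14822, Ccnb2 265, Chac1 176, Ptprc 284, Rplp0 14894, Tyrobp 456, Dcx 10329, Sall3 907 and Rrm2 513, and list means of 3.47 for the olfactory bulb and 3.23 for blood cells. P14 KO replicate 1 did so in 8: Grin2b 4837, Gria2 15158, Camp 2.17, Aif1 54.3 and Slc17a6 6233, and list means of 2.54 (granule neurons), 1.62 (Purkinje cells) and 2.93 (monoaminergic and cholinergic neurons). P25 WT replicate 3 did so for Slc6a3 2025, Car2 6168, Fshb 452, Cga 1109 and the pituitary list (7.43). At P14, KO replicate 2 stood apart for Hba-a2 2782 and the blood list (0.56), KO replicate 5 for Clic6 10.5, Ccnb2 51.4 and Ccdc153 1.05, WT replicate 1 for Hcrt 156 and WT replicate 6 for Ccdc153 9.69. At P25, KO replicate 2 stood apart for Gm26917 2164 and Cga 0.897, KO replicate 4 for Rps16-ps2 89.8 and Tbx21 557, WT replicate 2 for S100a8 0 and S100a9 0, WT replicate 4 for Mvk 509 and WT replicate 5 for Rplp0 4791.

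Libraries of the same age, genotype and batch differed in markers of brain regions. Genotype, age or batch cannot be the whole source, because Cbln3 differed up to 1891-fold between libraries of 1 group and batch (P25 KO, second batch), and read totals differed by a factor of only 1.48. Different parts of the brain in different libraries stay open as an explanation. The lowest forebrain-rich library lay 5.35 log2 units above the highest cerebellum-rich P25 library in the mean of Emx2, Lhx2 and Nr2e1, but this gap does not decide it, since the genes were picked after the pattern was seen and the libraries were grouped by regional markers. The labels call the tissue whole brain for every library, and no biological explanation was tested. In the second batch all 3 P25 WT libraries and no P14 WT library were cerebellum-rich, so part of the WT age effect cannot be told apart from this difference.

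P14 WT replicate 5 held transcripts foreign to brain. Blood alone was argued against, since Col1a1, a collagen gene of connective tissue and bone, lay 5.71 log2 units above the next library (134455 against 591 to 2571 in the other 23). Bone (8 genes, such as Ibsp at 3976) lay 5.67 units and olfactory mucosa (7 genes, such as Omp at 40401 and Cyp2a5 at 42165) 6.36 units above the next library, so tissue from the nasal cavity or skull next to the olfactory bulb is a candidate source. Without this library 12 lists instead of 16 passed for KO against WT at P14, of which 7 were among the 16, and Shank2 passed at P25 (adjusted p = 0.0464). No biological explanation was tested.

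Shank2 was lower and Gm26793 higher in KO at both ages. Among forebrain-rich P25 libraries (2 WT, 2 KO) Gm26793 differed by 4.07 (SE 0.73) against 2.91 (SE 0.56) in all. Neither passed (limma adjusted p = 0.0506 and 0.446). Striatal lists differed there (2.93 and 2.21 in WT, 0.10 and −0.12 in KO), so that fit cannot decide. In forebrain-rich P14 libraries Gm26793 was 54 to 56 in KO and 0 to 9 in WT. Shank2 was 3886 to 6458 in KO and 7412 to 12778 in WT. Both argue against regional makeup as source there. A local effect of the deletion, or of DNA that travelled with it in breeding, cannot be told apart from a separate effect. With Shank2, Gm26793 and LTO1 left out, 2 of 36 genes in the window (5.6%) had an unadjusted p under 0.05 at either age, Trpm5 (−0.97, SE 0.42) and Ccnd1 (−0.38, SE 0.17) at P14, a share above that of 77.2% of 17446 other windows. This test was changed after its first outcome, since its first version counted the genes that had prompted it.

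Other splits of the same libraries were counted, 100 per result with the real split included. KO against WT gave 0 genes in the real split at P14, at P25 and for the difference between ages. All 100 splits are as large as a count of 0 whatever they give, so these 3 counts say nothing about chance; the highest other counts were 4090, 52 and 2 (limma, with 554, 98 and 189 genes at an unadjusted p under 0.05, while edgeR and limma-voom also called 0 and DESeq2 1, 5 and 1). For lists the real counts were 16, 22 and 20, with 71, 13 and 32 splits as large and highest other counts of 29, 26 and 29, so chance is not excluded for any of these list counts. For age in WT the real split gave 5134 genes, 1 split was as large (the real one) and the highest other gave 4924. Without P25 WT replicate 5 or 4 the real count fell under that value (3289 and 3402 genes, with no splits counted for those fits). The splits therefore do not settle whether chance is excluded for this count. Its 15 lists were matched by 75 splits (highest other 30). For age in KO 5 splits were as large as the 2163 genes (highest other 4635), so chance is not excluded there. A split can keep most libraries in their true age group, and the split that called 4924 genes was not examined. Its count is therefore not assigned to a source. Splitting by batch in place of age gave 0 genes in WT and 0 in KO. The model of that split kept its batch terms, then estimated from the other genotype, and took them out of the contrast. These 0 counts therefore do not tell whether batch alone yields calls.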

How the results depend on the processing

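Surrogate variables, region covariates, the forebrain-rich and cerebellum-rich subsets and the list tests without single libraries were chosen after seeing the data, and the cause was not tested for the differences given here unless named. Genes called for KO against WT, 0 at each age and 0 for the difference between ages in limma (554, 98 and 189 unadjusted), were 1, 5 and 1 with DESeq2. Surrogate variables gave 2 at P14 and 1 at P25, region covariates 1 at P25, and forebrain-rich libraries only, with 2 WT against 2 KO libraries at P25, 85 at P25 and 36 for the difference. All other settings gave 0, edgeR and limma-voom among them (818 and 567 unadjusted at P14, 172 and 106 at P25). The 5134 genes for age in WT became 1649 with no batch term, 53 in the first batch only, 6163 in the second only, 1376 with surrogate variables, 864 with region covariates and 2318 in forebrain-rich libraries only. The 2163 genes for age in KO became 3316 with DESeq2, 1311 with no filter, 444 with no batch term, 334 with only the groups compared, 45 in the first batch, 0 in the second (4754 unadjusted) and 3254 in forebrain-rich libraries only. EdgeR gave 1318 up and 860 down there (60.5% up, against 49.8%). Shank2 fell past the threshold with surrogate variables (−1.17 at P14 and −1.22 at P25), DESeq2 (−1.29 at P25) and region covariates (−1.13 at P25), and was lower in KO under every setting run. Leaving out each library in turn gave 0 to 0 genes at P14, 0 to 1 at P25, 0 to 0 for the difference, 3289 to 6585 for age in WT and 812 to 6858 for age in KO. Shank2 then ran from −1.18 to −0.76 at P14 and from −1.46 to −1.25 at P25. Lists then ran from 6 (without P14 WT replicate 3) to 21 at P14, 14 (without P25 KO replicate 4) to 22 at P25, 15 to 24 for the difference and 12 to 17 for age in WT. With an estimated correlation 0 lists passed at P14, 0 at P25, 0 for the difference and 0 for age in WT, and with fry 0, 0, 0 and 6. Region covariates gave 24 lists at P14 (11 higher, 13 lower), against 16 (3 and 13). Surrogate variables gave 10 lists at P14, 13 at P25 and 9 for age in WT, and at P25 no filter gave 14 and the first batch only 14. Some named genes changed sign. In the first batch only these included genes at P25 that had not passed, such as Grin2b (−0.95, against 0.45) and Cartpt (−0.10, against 2.12). The genes that follow had passed in at least 1 setting. In forebrain-rich libraries only, these were Slc18a3 for the difference (−3.24, also −1.09 in the first batch and −0.42 with region covariates) and, for age in WT, Crabp1 (0.87), Etv1 (−0.50), Cartpt (0.13), Tyrobp (0.15) and Laptm5 (0.04). With surrogate variables they were Gm14033 (−0.31), Igfbpl1 (0.48), Crabp1 (0.26), Car4 (−0.44), Etv1 (−0.15), Tyrobp (0.04), Dcx (0.06), Trh (0.48), Sall3 (0.93) and Icmt (−0.08). In the first batch only they were Car4 (−0.18), Cartpt (0.15), Tyrobp (0.10) and Scn3a (0.03). The pituitary list could not be tested in the second batch only, in forebrain-rich or cerebellum-rich libraries only or without P25 WT replicate 3. The labels give WT and KO libraries of the same number and age a shared animal code prefix (1 prefix covers numbers 4 and 5 at P14) without saying what it marks, so a shared litter or cage is left open. Same-numbered libraries had correlations of −0.60 to 0.86, not all over 0.1, and only P14 number 2 and P25 number 6 matched best with their own number, so the libraries were not treated as pairs. The replicate block gave 0 genes in each KO comparison and 16, 22 and 19 lists. Within each group no 2 libraries were copies of each other (smallest chi-square per degree of freedom 5.9), and pairs between groups were not compared. Depth limits genes near the filter, such as Gm26793 at a mean of 0.548 CPM.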

Other observations

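The forebrain-rich subset was chosen after seeing the data. Among these libraries at P25, limma called 85 genes in KO against WT, 7 higher and 78 lower, and 13 of the lower ones are markers of striatal projection neurons, which carry dopamine signals through the basal ganglia. They include the adenosine receptor gene Adora2a (−4.71, SE 0.31), the dopamine receptor gene Drd1 (−2.76, SE 0.25), the signalling regulator gene Rgs9 (−3.07, SE 0.23) and Ppp1r1b (−3.38, SE 0.36), with adjusted p of 0.000289 to 0.00391. The acetylcholine genes Chat (−3.74, SE 0.43), Slc5a7 (−2.55, SE 0.24) and Slc18a3 (−3.48, SE 0.40) were lower as well. These calls rest on WT replicates 1 and 2, whose striatal list stood at 2.93 and 2.21, against KO replicates 1 and 3, at 0.10 and −0.12. In cerebellum-rich P25 libraries only (3 WT, 2 KO) limma called 0 genes (442 unadjusted) and camera 24 lists, 15 higher and 9 lower.

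Of the 40 lists, 9 passed camera in none of the 4 comparisons with the model used throughout, though all 9 passed in at least 1 comparison under at least 1 other setting. For KO against WT at P14 and P25 the means were −0.03 (adjusted p = 0.504) and 0.03 (0.888) for astrocytes, 0.07 (0.432) and −0.02 (0.553) for calcium and plasticity signalling, and 0.05 (0.556) and 0.27 (0.355) for cortical and hippocampal excitatory neurons. They were 0.14 (0.0618) and 0.05 (0.889) for inhibitory GABA-A receptors, 0.18 (0.102) and 0.38 (0.127) for GABAergic interneurons, and 0.16 (0.0618) and 0.05 (0.534) for metabotropic and kainate glutamate receptors. They were 0.11 (0.278) for NMDA receptor subunits and 0.03 (0.888) for postsynaptic scaffolds at P25, and −0.02 (0.514) and 0 (0.711) for synaptic vesicle genes. At P14, 6 of the 9 passed upward with region covariates: calcium signalling (0.22, 0.0002), cortical and hippocampal neurons (0.35, 0.00116), GABA-A (0.26, 0.00012), metabotropic receptors (0.24, 0.000185), scaffolds (0.20, 0.000113) and synaptic vesicle genes (0.13, 0.000952). With surrogate variables 2 passed downward, calcium signalling (−0.16, 0.00369) and synaptic vesicle genes (−0.13, 0.0018). Forebrain-rich libraries only gave 3 upward and 1 downward, the second batch 3 upward and the first 1 downward. At P25, 5 passed downward and 1 upward in forebrain-rich libraries only, 6 upward in cerebellum-rich libraries only, 3 upward with region covariates and 0 with surrogate variables. At P25 some of these lists passed in single batches, with opposite signs in the first and second: cortical and hippocampal neurons −0.82 (0.0079) and 1.36 (2.73e-05), calcium signalling −0.43 (0.00539) and 0.40 (0.0244), and astrocytes 0.17 (0.0294) and −0.11 (0.0349). Interneurons were at −0.54 (0.0548) and 1.30 (0.00349) and scaffolds at −0.25 (0.068) and 0.31 (0.0102). List mean, median and test differed in sign for synaptic vesicle genes at P14 (−0.02, 0.05, up), and at P25 for immediate early (0.08, 0.03, down) and GABA-A genes (0.05, −0.04, down). For the difference between ages they did so for interneurons (0.20, −0.02, down), NMDA subunits (0.04, −0.02, up) and synaptic vesicle genes (0.02, −0.09, down). For age in WT they did so for calcium signalling (−0.10, −0.11, up), metabotropic receptors (0.06, −0.18, down), nuclear noncoding RNAs (−0.19, 0.14, up) and NMDA subunits (−0.10, 0.16, down).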
